A study of Mus musculus with 798 samples.

How the data were processed

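The series measured gene expression in mouse EpiSC-5 cells, a line of epiblast stem cells, which resemble the epiblast after implantation (the primed state of pluripotency). Per the labels' protocols, the cells grew on Matrigel in medium conditioned by mouse embryonic fibroblasts and filtered, with added bFGF and Activin. They were transduced with lentiviral short hairpin RNAs (shRNAs) of the MISSION library, selected with puromycin, and lysed for PLATE-Seq, a 3'-tag RNA-seq method in which the wells of a plate are barcoded and pooled. Of 798 wells on 13 plates, 613 held a hairpin against 1 of 154 genes, 149 a non-targeting control and 36 were mock wells, which were on 4 of the plates. The labels give 600 different hairpin clones. They name no separate cultures, so p-values measure the spread between wells, which may be technical.

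The deposited values are raw counts per gene, whole numbers for 24076 Entrez gene IDs in each well, per the file headers and the values. STAR and the build GRCm38 (mm10) are named in the submitters' processing notes; the counter, the gene annotation, the use of molecular identifiers and of strand are not given in the sources used here. Symbols of 24014 IDs came from a gene table of GRCm38.p6, and gene positions from GENCODE annotation of that build. Without known strand use, overlapping genes cannot be told apart. Each file was taken as 1 well, and the wells were grouped by target, clone and plate from the labels. No pair of wells among 1100 compared agreed within sampling noise (lowest chi-square per degree of freedom 5.78), so no library was taken as a repeat deposit. No gene of the mitochondrial chromosome is in the table. A 3' tag counts a transcript at its 3' end only, so a hairpin's target can be read there where it has counts.

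All tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, glmQLFit without the legacy option and glmQLFTest, with plate as covariate and Benjamini-Hochberg adjustment at 0.05. Targeted genes with at least 10 counts over a fit were always kept. Wells under 100000 counts were left out (3 wells), and a target needed 3 wells. Each target was set against the non-targeting wells of its own plates; 134 targets could be fitted. Log2 fold changes are given with standard errors derived from the F statistic. Comparisons described one by one were the non-targeting against mock wells, the non-targeting wells with no clone named against the named control hairpins, the control Shc001 against Shc002 and Shc202, the knockdowns of Pou5f1, Sox2, Nanog and Otx2, and the 4 further targets with most calls among those with at least 4 wells, at least 2 clones and a lower fitted level of their own transcript. Targets are therefore not a random sample where chosen by their calls, and targets on a plate share its control wells.

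Gene lists were written from general knowledge before the data were examined: core, primed epiblast and naive pluripotency, primitive streak, definitive endoderm, mesoderm, neural ectoderm, trophoblast, germline, fibroblast, interferon response, p53 response, integrated stress response, endoplasmic reticulum chaperones, heat shock, mitosis, DNA replication, Myc and nucleolar genes, ribosomal proteins, glycolysis and hypoxia, cholesterol synthesis, targets of Nodal and Activin, of FGF and ERK, of Wnt and of BMP, actin and YAP targets, and mitochondrial transcripts, none of whose 26 names is in the table. A list was tested with at least 5 measured members by cameraPR (limma 3.58.1, preset correlation 0.01), and again by camera with the correlation estimated from log2 CPM (prior count 2). List p-values were adjusted over the lists of 1 comparison for the comparisons described one by one, and over all targets and lists for the screen. Named genes are the targeted gene, the 8 largest rises and 8 largest falls among called genes with a mean of at least 20 CPM and 1 sign in every target well (for controls in every plate), and the 4 members with smallest p of each called list. For the screen they are the 10 targets with the largest fall of their transcript and the 10 with most calls. Some genes that meet these rules are not reported here. Where a transcript had 0 counts over a group, a lower bound of the fold was computed against 3 counts over the group; bounds cover counting error only. The agreement of hairpins was the mean Pearson correlation, across genes with a mean of at least 50 CPM, of log2(CPM + 10) deviations from the control wells of the plate, set against 1000 shuffles of wells within plates.

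Alternatives were RLE size factors, DESeq2 1.42.0, the older edgeR pipeline (estimateDisp and the legacy option), no filter on low counts, no depth minimum or 300000 counts, no plate term, named or unnamed controls or hairpin wells of other targets as reference, and each target well left out in turn. Mock wells as reference, and control wells 93 to 95 of each plate left out, were added after the data were seen. The tests were run on simulated counts with 200 changed genes, 100 by 4-fold and 100 by 2-fold. In these, 23.9% of the main test's calls were false for the comparison with mock (9637 genes), 23.7% for the unnamed controls (9155), 33.3% for Pou5f1 (11515), 18.0% for Nanog (11209) and 28.9% for Otx2 (10920). With no change simulated it made 3, 0, 15, 1 and 18 calls, and the older pipeline 0 in each. The main test was kept as fixed, and counts also called by the older pipeline are given beside it. It recovered 4-fold changes in 100, 100, 50, 58 and 92 of 100 genes and 2-fold changes in 91, 96, 16, 24 and 53. As a check on the controls, 100 sham targets drawn from non-targeting wells gave a median of 0 and at most 2 genes, but 50 of them had at least 1 list called within the draw (at most 11, 175 in all). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.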

Results

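Expression was measured by PLATE-Seq in 798 wells of EpiSC-5 cells on 13 plates. A hairpin against 1 of 154 genes, chosen as candidate regulators of pluripotency, was in 613 wells, with a median of 3 wells and at most 8 wells per gene. A non-targeting hairpin or empty vector was in 82 wells with no clone named and 67 with a named clone, and 36 were mock wells. The total count per well had a median of 1122431 (range 76 to 2619901), with 1091623 in non-targeting wells (414037 to 2222622) and 1275738.5 in mock wells (634015 to 2050324). A median of 11945 genes was detected per well, and the 10 most abundant genes took a median of 9.12% of the counts. The totals were under 100000 in 3 wells, replicate 3 of each of the Hes6, Zmat4 and Smad2 knockdowns, which were left out. Transcripts of few counts are therefore measured only coarsely in single wells.

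The first question was whether the hairpins lowered their own targets. The targeted transcript was lower than in the non-targeting wells of the same plates for 55 targets (42.6% of those measured, adjusted over targets). Its fitted change was negative for 83.7%, and the median log2 fold change was -1.18. By contrast, only Sp6 was higher (log2 fold change 2.30, adjusted p = 0.012). Among the 10 largest falls, Cited1, a transcriptional coregulator, had 0 counts in all 5 of its wells against 18.4 ± 20.8 CPM in 25 control wells (SD), a level at least 30.8-fold lower (adjusted p = 0.0058 over targets). The zinc-finger gene Zfp334 had 0 counts in all 6 wells and was at least 19.9-fold lower than in 21 control wells (6.96 ± 12.7 CPM, adjusted p = 0.0073). Zfp518b had 1 count over 4 wells, with a log2 fold change of -6.02 ± 1.69 (SE, adjusted p = 0.0028) against 18.3 ± 16.3 CPM in 27 control wells. Rcor2, a subunit of a corepressor complex, was at 0 in 3 wells and at least 11.2-fold lower (9.19 ± 14.3 CPM in 31 control wells, adjusted p = 0.080), Gbx2, a homeobox factor, at 0 in 3 wells and at least 7.16-fold lower (adjusted p = 0.19), and Aebp1 at 0 in 6 wells and at least 5.96-fold lower (adjusted p = 0.13). Control wells themselves often had 0 counts: 9 of 25 for Cited1, 9 of 21 for Zfp334, 15 of 31 for Rcor2, 7 of 9 for Gbx2 and 19 of 27 for Aebp1.

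Some of the largest falls came from targets with 1 or 2 wells, which have no test here. Tfam, the transcription factor of mitochondrial DNA, had 0 counts in its 1 well, at least 6.88-fold below the 63.4 ± 23.2 CPM of 16 control wells. Hey1, a Notch effector, had 0 counts in 1 well (at least 3.62-fold lower) and Zfp46 0 in both wells (at least 4.93-fold lower). Well-measured falls, chosen after their values were seen, included Hmga1, an architectural chromatin protein (-4.38 ± 0.37), Tcf7, a Wnt effector (-3.60 ± 0.43), and Hdgf (-2.73 ± 0.19). Tgif2 shares 56.7% of its exonic bases with another gene. Ecsit, Eno1b, Sox2, Tgif2 and Zfhx2 had too few counts in their fits to be measured.

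**Figure D1:**
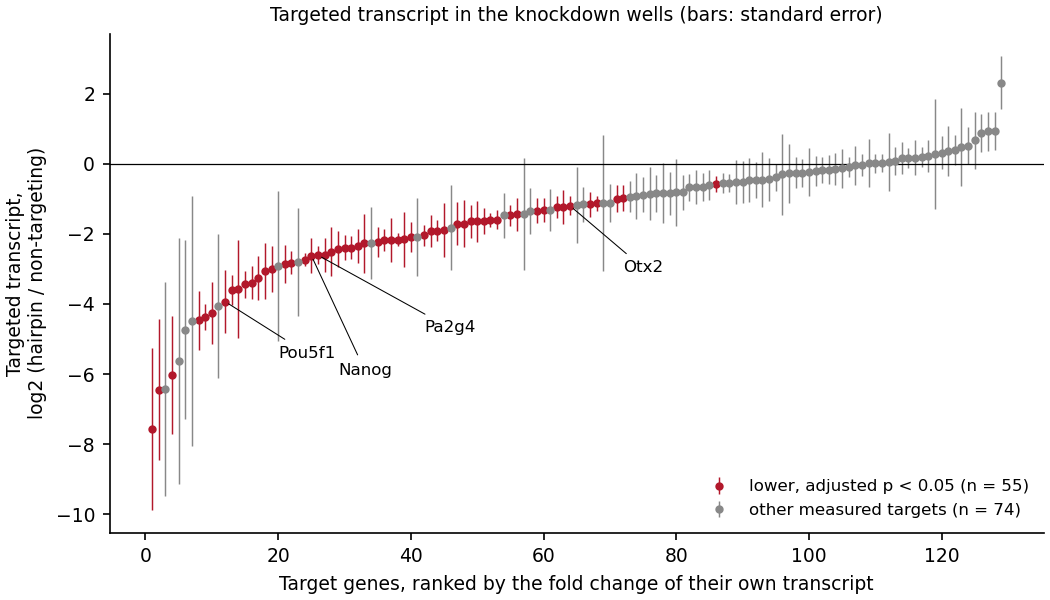
Log2 fold change of the targeted transcript (vertical axis, error bars SE) for each measured target, ordered by its value; 55 targets are marked as lower at an adjusted p under 0.05 over targets and the other 74 are not. Most values lie below 0.

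The second question was which knockdowns altered the transcriptome. Of the targets fitted, 64 (47.8%) had at least 10 genes called and 8 at least 100, with a median of 8 and a maximum of 1276 for Pou5f1. After it came Myc (286), Etv1 (257), Pa2g4 (217), Nanog (161), Otx2 and Psmc3ip (140 each), Zscan10, Pou6f1 (96) and Nfatc3 (90). The Myc transcript itself had a positive fitted change in its knockdown (log2 fold change 0.51). The lists that moved most often were Myc and nucleolar genes (lower in 78.4% of targets), heat shock (lower in 60), DNA replication (lower in 59), actin and YAP targets (higher in 56), primed epiblast (lower in 51), integrated stress response (lower in 50, higher in 3), mitosis (higher in 49, lower in 7), ribosomal proteins (lower in 47, higher in 5), glycolysis and hypoxia (higher in 30, lower in 20) and core pluripotency (lower in 44). These calls are adjusted over all targets and lists, unlike those of the single knockdowns below, so a list can pass there and not here. With an estimated correlation, Myc and nucleolar genes, primed epiblast and core pluripotency were each lower in 2 targets and DNA replication in 1. The other lists just named had 0 calls with it.

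FGF and ERK targets were lower in 38 targets and higher in 1, primitive streak higher in 28 and lower in 4 (not tested in 2), definitive endoderm higher in 24 and lower in 3 of 97 tested, Nodal and Activin targets lower in 23 and higher in 6, and the p53 response higher in 22 and lower in 2. With an estimated correlation, the primitive streak was higher in 7 and definitive endoderm in 4, and the other lists of this paragraph lost all their calls. The remaining lists were called in few targets. Cholesterol synthesis was lower in 11 and higher in 7, neural ectoderm lower in 10 and higher in 2, fibroblast higher in 9 and lower in 1, trophoblast higher in 7, Wnt targets lower in 7, BMP targets higher in 3 and lower in 2, endoplasmic reticulum chaperones lower in 5, mesoderm higher in 3 of 18 tested, the interferon response higher in 2 and lower in 1, and naive pluripotency lower in 2. Germline genes could be tested in 1 target, with no call, and mitochondrial transcripts in 0. Over 3196 tests of a list in a target, 257 were higher and 552 lower (25.3% called), but with an estimated correlation 11 and 7. In sham targets drawn from non-targeting wells, 4.99% of 2324 such tests were called, 48 higher and 68 lower. With hairpin wells of other targets as reference, Myc and nucleolar genes were higher in 13 targets and lower in 7, the primitive streak in 12 and 12, definitive endoderm in 5 and 7, and mitosis in 10 and 14. Over all lists 152 tests were higher and 1.1e2 lower with that reference, and the number of targets with at least 10 genes was 24. The older edgeR pipeline gave 22 such targets, no filter on low counts 79.1% of targets, named controls 100 and unnamed controls 42.

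The non-targeting reference holds wells 93 to 95 of each plate, which stand apart from the others. Without them, a choice made after the results were seen, 93 targets had at least 10 genes called and 53 had a lower targeted transcript. Fibroblast genes were then higher in 85 targets and trophoblast genes in 82, while heat shock was lower in 3 and higher in 2. With an estimated correlation trophoblast genes were higher in 6, fibroblast genes in 2 and the primitive streak in 4. Myc and nucleolar genes were lower in 87 and mitosis higher in 14 and lower in 13. Over all lists 353 tests were higher and 503 lower (15 and 15 with an estimated correlation). In sham targets drawn without these wells 0.91% of list tests were called. Glycolysis and hypoxia was higher in 1 and lower in 41, and definitive endoderm in 15 and 15 of 84 tested. FGF and ERK targets were lower in 9, ribosomal proteins in 81 and primed epiblast in 55. Primed epiblast apart, the list counts named here therefore depend, to differing degrees, on 3 control wells per plate.

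**Figure D2:**
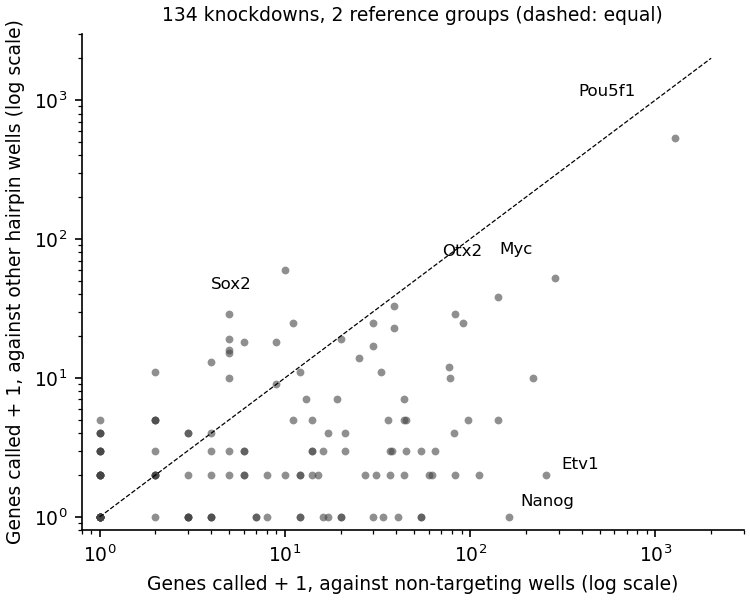
Genes called plus 1 (log scale) for each knockdown fitted, with non-targeting wells as reference on the horizontal axis and hairpin wells of other targets on the vertical axis. Pou5f1 has 1276 and 536 genes, and Nanog 161 and 0.

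The non-targeting wells served as the reference throughout, so they were compared with mock wells on the 4 plates that held both. Compared with 36 mock wells, 65 non-targeting wells had higher Nodal and Activin targets and Myc and nucleolar genes, and lower mitosis genes. The treatment of the mock wells is not given, so effects of virus, selection and hairpin are not separated here. Position differed as well: 31 of the 36 mock wells were numbered 1 to 8, and 38 of the 65 non-targeting wells 80 or higher. Lefty2, a Nodal inhibitor, reached 114.8 ± 123.9 CPM against 34.8 ± 19.1 CPM (SD, log2 fold change 1.61 ± 0.25, SE), its relative Lefty1 203 ± 77.8 against 121.4 ± 55.7 (0.81 ± 0.12), and the Nodal co-receptor Tdgf1 258 ± 126.8 against 121.5 ± 53.8 (1.05 ± 0.15). Slc2a3, a glucose transporter, was at 3414 ± 1051 CPM against 5868 ± 963 (-0.83 ± 0.08). In all, edgeR called 1065 higher and 1164 lower genes of 10245, with a median size of 0.53, and the older pipeline also called 1239 of these 2229.

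The largest rises with 1 sign on all 4 plates were Psors1c2 (1.98 ± 0.19), Trh, the thyrotropin-releasing hormone precursor (1.71 ± 0.18), Morc2a (1.65 ± 0.30), Lefty2, Polr1e, a subunit of RNA polymerase I (1.49 ± 0.19), Fgf15 (1.39 ± 0.15), Apba2 and Cd3eap. The largest falls were Acsl3, a fatty acid activating enzyme (-1.35 ± 0.18), the lysyl oxidase Loxl2 (-1.35 ± 0.21), Fam114a1, Mid1, Zfp944, Thsd7a and Adamts10. Of the 19 Myc and nucleolar genes 14 rose (15 adjusted over the list alone; list adjusted p = 1.5e-11, 8.8e-07 with an estimated correlation), among them the nucleoside kinase Nme1 (0.91 ± 0.11) and the polyamine enzymes Srm (0.62 ± 0.09) and Odc1 (0.58 ± 0.09). Of 12 Nodal and Activin targets 7 rose (8 adjusted over the list alone, adjusted p = 8.0e-05, 0.014 with an estimated correlation). Of 19 mitosis genes 11 fell (11 adjusted over the list alone, adjusted p = 2.8e-07, 0.028 with an estimated correlation), including Cenpf (-0.82 ± 0.11) and Nusap1 (-0.61 ± 0.10), of the kinetochore and spindle.

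Other calls were lost with an estimated correlation. Of 21 glycolysis and hypoxia genes 9 fell (11 adjusted over the list alone), including Aldoa (-0.52 ± 0.07) and Ero1a (-0.83 ± 0.11), with an adjusted p of 0.17 with an estimated correlation. Of 24 ribosomal proteins 9 rose (11 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation), and in the following brackets the count adjusted over the list alone precedes the adjusted p with an estimated correlation. Of 16 primed epiblast genes 5 rose and 2 fell (5 and 2, p = 0.22), of 12 core pluripotency genes 4 rose (4, p = 0.22), of 17 genes of the integrated stress response 6 rose (7, p = 0.17), of 12 heat shock genes 5 rose and 1 fell (6 and 2, p = 0.15), of 15 FGF and ERK targets 5 rose (7, p = 0.17), and of 17 p53 response genes 4 rose and 1 fell (5 and 1, p = 0.11). The fall was that of Btg2, an antiproliferative gene (-0.42 ± 0.09), beside rises of Ccng1 (0.78 ± 0.08) and of the cell cycle inhibitor Cdkn1a (0.53 ± 0.11). The older pipeline kept the calls of 52 of the 57 named genes; with only unnamed non-targeting wells against mock, 1419 genes were called.

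The non-targeting wells were not uniform. Wells 93 to 95 of each plate, 39 in all, were set against the 110 other non-targeting wells of the 13 plates after the results were seen. They had 2597 higher and 2489 lower genes of 10952, with a median size of 0.63. The labels give them the same treatment, the median totals were alike (1094104 and 1085380), and the cause is not known. Col1a1 was at 382 ± 340 against 11.1 ± 15.9 CPM (4.92 ± 0.14), Mmp9 at 79.7 ± 47.6 against 2.32 ± 6.39 (5.20 ± 0.24) and Trh at 87.0 ± 42.7 against 581 ± 280 (-2.83 ± 0.14), each with 1 sign on all 13 plates. Glycolysis and hypoxia genes fell in 17 of 21 and rose in 1 (17 and 1 adjusted over the list alone; adjusted p = 7.2e-06 with an estimated correlation). Trophoblast genes rose in 8 of 9 (9, p = 1.7e-04), heat shock genes in 10 of 13 (11, p = 3.2e-04), and fibroblast genes in 6 of 7 with 1 lower (6 and 1, p = 0.0021). On the 4 plates with mock wells, 2321 genes were called without these wells, 1766 of them among the 2229, and Lefty2 had 0.82 in place of 1.61.

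Of the named control wells 38.8% were wells 93 to 95, and of the unnamed 15.9%. Without them edgeR called 42 genes between the 2 kinds (27 higher, 15 lower), and only Trh, Crabp1, Srpr and Arglu1 kept their call among the 41 called named genes. The median size of the 1444 changes described next was 0.17 (median SE 0.17) in place of 0.45 (0.12), so most of that difference goes with these wells. Against 67 wells with a named control hairpin, the 82 wells with no clone named had 715 higher and 729 lower genes of 9781 on the 13 plates, with a median size of 0.45. Trh was higher (585 ± 357 against 295 ± 185 CPM, log2 fold change 1.23 ± 0.21). So were Crabp1 (0.91 ± 0.16), Rrm2b (0.91 ± 0.15) and Cd24a (0.69 ± 0.12). Nlrp4e (-1.20 ± 0.21), Srpr, the signal recognition particle receptor (-1.11 ± 0.14), the metallothionein Mt2 (-1.02 ± 0.17) and Arglu1 (-0.83 ± 0.10) were lower. Each of these had 1 sign on all 13 plates. Without a plate term 889 genes were called, and with RLE size factors 562 were higher and 904 lower; 760 were also called by the older pipeline.

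Of 24 ribosomal proteins 8 rose in the unnamed controls (11 adjusted over the list alone), led by Rpsa (0.25 ± 0.04), but the list had an adjusted p of 0.22 with an estimated correlation. Without wells 93 to 95 this call was lost, with Rpsa at 0.055. Glycolysis and hypoxia, below, was then called lower (adjusted p = 9.7e-05), though not with an estimated correlation. The heat shock, Myc and chaperone lists turned without a call. Rplp0, with a log2 fold change of 0.36 ± 0.06, turned to -0.15 without a plate term. In the next brackets the count adjusted over the list alone precedes the adjusted p with an estimated correlation. Of 17 p53 response genes 3 rose (5, p = 0.13), Ccng1, Btg2 and Cdkn1a, and of 21 glycolysis and hypoxia genes 6 rose (6, p = 0.29), including Ldha (0.51 ± 0.10). Lower counts were seen for the integrated stress response with 3 of 18 (4, p = 0.13), Myc and nucleolar genes with 4 of 19 (5, p = 0.30), heat shock with 3 of 12 (3, p = 0.29), endoplasmic reticulum chaperones with 2 of 17 (2, p = 0.22) and trophoblast genes with 2 of 6 (3, p = 0.22).

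Within the named controls, 12 wells of Shc001, the empty vector, were compared with 34 wells of Shc002 and Shc202 on 4 plates. edgeR called 0 of 10349 genes, with 986 at an unadjusted p under 0.05, while the older pipeline called 1 and DESeq2 38 (12 higher, 26 lower); without a filter on low counts edgeR called 27 (7 and 20). The collagen genes Col1a2 (7.23 ± 8.23 against 79.0 ± 119.8 CPM, adjusted p = 0.061) and Col1a1 (adjusted p = 0.067) and the tropomyosins Tpm1 and Tpm2 (each adjusted p = 0.061) had lower fitted values. The fibroblast list (0 of 6 members called, 2 lower adjusted over the list alone), the trophoblast list (0 of 6, 4 lower) and the actin and YAP targets (0 of 15, 1 higher and 3 lower) were called lower, and ribosomal proteins (0 of 24 in both counts) higher. With an estimated correlation their adjusted p was 0.47, 0.47, 0.47 and 0.81. The Shc002 and Shc202 wells include 8 of wells 93 to 95. Without those, 1 gene was called, none of the 4 lists was, and Col1a2 had a log2 fold change of -0.99.

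Pou5f1 (Oct4) is the central transcription factor of pluripotency. Its transcript was at 0, 13.7 and 0 CPM in the 3 knockdown wells against 74.9 ± 48.1 CPM in 31 control wells (log2 fold change -3.93 ± 0.90, adjusted p = 0.0021). Without replicate 1, and with it the 16 control wells of its plate, the value was -2.67 and the call was lost. In these wells the core pluripotency list was called lower, and the primitive streak, definitive endoderm, mesoderm and neural ectoderm lists higher. Utf1, a chromatin factor of pluripotent cells, was at 9.01 ± 8.39 against 884 ± 351 CPM (log2 fold change -6.65 ± 0.58), the RNA-binding protein L1td1 at 7.10 ± 8.58 against 160.3 ± 120.4 CPM and the Nodal co-receptor Tdgf1 at 12.0 ± 16.9 against 252 ± 136.5 CPM. The nuclear receptor Nr2f2 rose to 1157 ± 548 against 14.5 ± 33.0 CPM (5.92 ± 0.44) and Acta2, smooth muscle actin, to 3191 ± 3540.0 against 43.1 ± 47.3 CPM (5.86 ± 0.42).

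The other large rises were Capn6, a calpain-related protein (6.84 ± 0.40), the forkhead factor Foxq1 (6.21 ± 0.47), Ikzf2 (4.43 ± 0.38), the matrix proteins Tnc (4.40 ± 0.61) and Col4a2 (3.82 ± 0.49), and the small heat shock protein Cryab (3.80 ± 0.59). The 8 largest falls by the naming rule had 0 counts in all 3 wells: Slc6a15, an amino acid transporter, was at least 79.5-fold lower, Zfp473 at least 42.3-fold, Alg14 at least 35.5-fold, and Ly6d at least 35.0-fold. The pluripotency factor Foxd3 was at least 34.3-fold lower, Cebpd at least 31.1-fold, Mup6 at least 29.4-fold and Actr5 at least 25.0-fold. Of 12 core pluripotency genes 7 fell and 1, Zfp462, rose (7 and 1 adjusted over the list alone). The list had an adjusted p of 2.7e-06, and 6.7e-05 with an estimated correlation. Pou5f1 itself is among the falls, and the list was not tested without it.

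Of 12 primitive streak genes 7 rose (7 adjusted over the list alone; adjusted p = 0.0056 with an estimated correlation), including Fgf8 (728 ± 427 against 100.0 ± 88.9 CPM), the organizer factor Gsc (4.29 ± 0.70) and Eomes (2.48 ± 0.56). Of 8 definitive endoderm genes 4 rose and Apela fell (4 and 2 adjusted over the list alone, p = 0.0030), with Foxa1 (5.54 ± 0.61) and Gata4 (4.62 ± 0.60) the best supported. Among 5 mesoderm genes 4 rose (4, p = 0.014), led by Foxc1 (3.95 ± 0.60), and among 12 neural ectoderm genes 4 (6, p = 0.016), led by the eye and neural crest factors Six3 (6.49 ± 0.62) and Pax3 (6.77 ± 0.66). BMP targets rose in 7 of 10 (7, p = 0.016), with the inhibitors of differentiation Id3 (2.83 ± 0.46) and Id1 (2.94 ± 0.60), and trophoblast genes in 6 of 12 (6, p = 0.24), among them Peg10 (2.17 ± 0.47), Gata3 (2.41 ± 0.53) and Krt7 (2.57 ± 0.58). Brackets give the count adjusted over the list alone and the adjusted p with an estimated correlation.

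Fibroblast markers rose in 6 of 10 (7 adjusted over the list alone; adjusted p = 0.021 with an estimated correlation), unevenly between wells: by the plain totals of the wells, Col1a1 was at 47.4, 733 and 3032 CPM and Acta2 at 499, 1829 and 6395 CPM, against control medians of 6.55 and 22.9. The highest control well had 622 CPM of Col1a1, and the highest for Acta2 was 174 CPM. Postn and Lum, also fibroblast markers, had 0 counts in all 3 wells. Actin and YAP targets rose in 9 of 16 (9, p = 0.052), with Flna (2.27 ± 0.25), Tpm1 (1.87 ± 0.23) and Tpm2 (2.23 ± 0.31).

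Ribosomal proteins fell in 14 of 24 (22 adjusted over the list alone; adjusted p = 0.021 with an estimated correlation), such as Rps12 (-1.29 ± 0.29), and glycolysis and hypoxia genes in 8 of 22 (10, p = 0.025), with the glucose transporter Slc2a1 (306 ± 13.9 against 1092 ± 299 CPM), Pgk1 (-2.73 ± 0.46) and Ldha (-1.65 ± 0.31). Myc and nucleolar genes fell in 4 of 20 (4, p = 0.036), among them nucleolin, Ncl (-1.03 ± 0.23), and Npm1 (-0.96 ± 0.22). Calls were lost with an estimated correlation for the next lists. Mitosis genes fell in 3 of 19 (5, p = 0.058), DNA replication genes in 2 of 19 (3, p = 0.058), cholesterol synthesis genes in 2 of 19 (2, p = 0.058) and interferon response genes in 2 of 8 (3, p = 0.054), the latter H2-K1 (-1.33 ± 0.30) and Ifitm3 (-1.08 ± 0.28).

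In total 859 genes rose and 417 fell of 12172 tested, with a median size of 1.90. The older edgeR pipeline also called 537 of these 1276, and 466 were also called with hairpin wells of other targets as reference. RLE size factors gave 1069 higher and 313 lower genes, and DESeq2 292 and 420. Without replicate 1 and its plate 482 genes were called, and without replicate 3, 574. The count was 2022 without control wells 93 to 95, where all 70 called named genes kept their call and the definitive endoderm list lost its own (adjusted p = 0.10). Of the 70 called named genes, 31 kept their call whichever well was left out. Lhx1 (4.71 ± 1.01), an organizer gene, had -0.04 against hairpin wells of other targets.

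**Figure D3:**
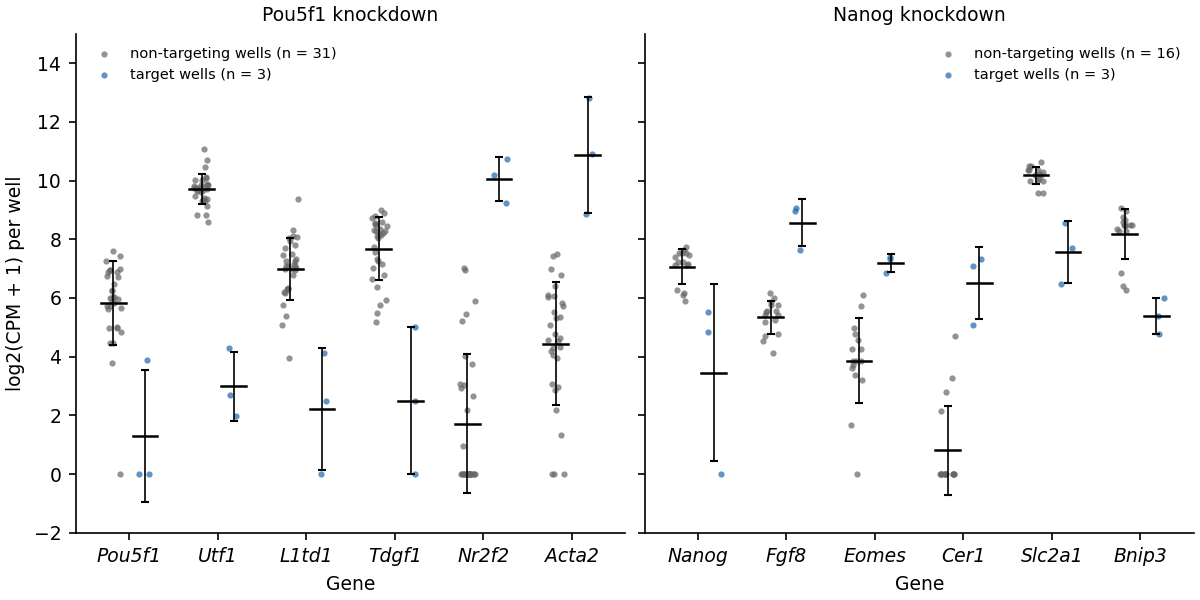
Expression as log2(CPM + 1) in each well of the Pou5f1 knockdown (Pou5f1, Utf1, L1td1, Tdgf1, Nr2f2, Acta2) and of the Nanog knockdown (Nanog, Fgf8, Eomes, Cer1, Slc2a1, Bnip3) and in the control wells of the same plates; points are wells, lines means and bars SD. The 3 wells of each knockdown lie on 1 side of the control mean for these genes.

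Nanog, a homeobox factor of pluripotency, was at 27.6, 0 and 44.7 CPM in its 3 wells against 142.99 ± 49.3 CPM in 16 control wells of its plate (log2 fold change -2.62 ± 0.50, adjusted p = 0.0028). Without replicate 2 the value was -2.11 and the call was lost. The primitive streak and definitive endoderm lists were called higher, and glycolysis and hypoxia lower. Fgf8 reached 411 ± 185 against 42.5 ± 15.0 CPM (3.29 ± 0.25), Eomes, a T-box factor of the streak, 147.2 ± 28.8 against 20.0 ± 17.6 CPM (2.90 ± 0.39), Cer1, a secreted Nodal antagonist, 108.7 ± 66.7 against 2.70 ± 6.52 CPM (5.59 ± 0.59), and the organizer factor Lhx1 95.7 ± 42.3 against 1.71 ± 4.87 CPM (5.91 ± 0.64). Slc2a1 was at 223 ± 143.8 against 1177 ± 231 CPM (-2.32 ± 0.26).

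Of 14 primitive streak genes 9 rose (11 adjusted over the list alone; list adjusted p = 6.6e-24, 1.4e-05 with an estimated correlation), among them also Cyp26a1, a retinoic acid degrading enzyme (5.54 ± 0.60). Of 9 definitive endoderm genes 6 rose (6, p = 0.0022), with Gata4 (4.70 ± 0.59) and Foxa1 (3.54 ± 0.66) as examples. Glycolysis and hypoxia genes fell in 8 of 22 (12, p = 0.014), including Aldoa (-1.24 ± 0.19), Tpi1 (-1.41 ± 0.24) and Bnip3, a mitophagy receptor induced in hypoxia (-2.85 ± 0.50). In brackets stand the count adjusted over the list alone and the adjusted p with an estimated correlation. Further large rises were the metalloprotease Adam19 (3.34 ± 0.33), Foxq1 (3.96 ± 0.54), the Activin inhibitor Fst (3.05 ± 0.50), N-cadherin, Cdh2 (2.69 ± 0.32), and the BMP antagonist Chrd (2.67 ± 0.43). The aldolase Aldoc (-5.08 ± 0.79), Micu3 (-3.16 ± 0.61) and the mitotic kinase Ttk (-3.11 ± 0.71) were among the largest falls.

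Lists whose call was lost with an estimated correlation had fewer members moving. Rises were seen in 3 of 8 fibroblast markers (3 adjusted over the list alone; adjusted p = 0.30 with an estimated correlation), of which Acta2 was at 243 ± 258 against 45.5 ± 40.1 CPM. They were also seen in 2 of 13 Nodal and Activin targets (3 and 1 lower, p = 0.067), 2 of 9 Wnt targets (2 and 1 lower, p = 0.13), and 1 of 9 BMP targets (2, p = 0.067). A rise of 1 gene was called among 10 trophoblast genes (4, p = 0.24), 18 p53 response genes, Cdkn1a (1.30 ± 0.26) (1, p = 0.11), and 20 genes of the integrated stress response, Atf4 (0.84 ± 0.21) (1, p = 0.16). Actin and YAP targets had 2 rises, Flna (0.78 ± 0.15) and Zyx (1.30 ± 0.30), and a fall of Ccn2 (-1.96 ± 0.47) among 16 (2 and 1, p = 0.30). Lists called lower had falls in 3 of 20 mitosis genes (6, p = 0.067), 1 of 19 cholesterol synthesis genes, Insig1 (1 higher and 5 lower, p = 0.079), 0 of 19 DNA replication genes (2, p = 0.22) and 0 of 24 ribosomal proteins (1, p = 0.32). Rps18 had -0.81 ± 0.22 (adjusted p = 0.064).

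edgeR called 161 genes of 11964, of which 71.4% were higher and 46 lower, with a median size of 2.00. Of these 161, 68 were also called by the older pipeline, while DESeq2 called 85 higher and 203 lower. Without replicate 1, and likewise without replicate 2, 74 genes were called. With hairpin wells of other targets on the plate as reference, 0 genes were called by edgeR, so none of the 43 called named genes kept its call. That reference holds replicate 1 of the Pou5f1 knockdown. The median size of the 161 changes was 1.05 there (median SE 0.54) in place of 2.00 (0.43), and Nanog had -1.99 ± 0.56. The primitive streak list kept its call there (adjusted p = 1.0e-06). With mock wells as reference 800 genes were called, with 83.2% of the 161 among them, and with unnamed controls only 24. Of the 16 control wells 3 are wells 93 to 95, in which Bnip3 was lower as well (-2.08 ± 0.09). Without them 474 genes were called, 157 of the 161 among them, and all 43 called named genes kept their call.

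Otx2, a homeobox factor of the primed epiblast, was lower in all 8 knockdown wells, at 162 ± 80.0 against 415 ± 186 CPM in 45 control wells on 5 plates (log2 fold change -1.20 ± 0.27, adjusted p = 0.0078). With named controls only, 10 wells all among those that stand apart, the value was -0.39 and was not called. Fgf15, a growth factor gene of the epiblast and neural tissue, fell to 16.8 ± 15.9 against 101.2 ± 59.0 CPM (-2.40 ± 0.47), the matrix protein Spon1 to 16.5 ± 11.5 against 80.4 ± 37.9 CPM (-2.12 ± 0.36) and Tmem59l to 12.8 ± 18.9 against 77.5 ± 49.4 CPM (-2.24 ± 0.48). Rnpc3, a protein of the minor spliceosome, rose to 104.6 ± 69.3 against 22.2 ± 14.4 CPM (2.27 ± 0.27), Zfpm2, a cofactor of GATA factors, to 77.5 ± 52.6 against 25.6 ± 16.8 CPM (1.69 ± 0.25) and Igfbp3, which binds insulin-like growth factors, to 146.6 ± 61.5 against 58.3 ± 36.6 CPM (1.55 ± 0.29).

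Of 16 primed epiblast genes 2 fell, Fgf15 and Otx2 itself (1 higher and 4 lower adjusted over the list alone). The list had an adjusted p of 0.0029, and 0.0077 with an estimated correlation. It includes the targeted gene and was not tested without it. The DNA replication list was called lower with 0 of 19 members called over all genes by edgeR and 6 over the list alone (adjusted p = 0.010 with an estimated correlation). Mcm6 had -0.54 ± 0.16 (adjusted p = 0.058). The remaining lists lost their call with an estimated correlation. Core pluripotency had a fall of Utf1 (-0.98 ± 0.17) among 12 (2 adjusted over the list alone; adjusted p = 0.12), glycolysis and hypoxia a fall of Slc2a1 (-0.76 ± 0.15) among 22 (1, p = 0.63), the primitive streak a rise of Cyp26a1 (2.43 ± 0.49) among 8 (4, p = 0.12), and actin and YAP targets a rise of Tpm1 (0.58 ± 0.14) among 16 (2, p = 0.071). Myc and nucleolar genes (0 of 20, 2 over the list alone, p = 0.16), ribosomal proteins (0 of 24, 0 over the list alone, p = 0.35), heat shock (0 of 13, 2 over the list alone, p = 0.35) and the integrated stress response (0 of 19, 0 over the list alone, p = 0.35) were called lower as lists only.

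In all 89 genes rose and 51 fell of 11496, with a median size of 1.34, and 36 of the 140 were also called by the older pipeline. DESeq2 gave 56 higher and 69 lower genes. With hairpin wells of other targets as reference 37 were called, 15 of them shared, Rnpc3, Zfpm2, Nckap1, Cyp26a1 and Otx2 included. The count was 90 without replicate 4, 88 without replicate 7 and 82 without replicate 8, 456 with named controls only and 355 without control wells 93 to 95, where all 21 called named genes kept their call.

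Sox2, the partner of Pou5f1, had 0 counts in its 5 knockdown wells and in the 33 control wells, so its knockdown could not be checked. In GRCm38.p6 the gene lies on chromosome 3, from 34650405 to 34652461, with 2057 exonic bases, inside the span of the long noncoding gene Sox2ot (34104270 to 34682619). Sox2ot had 5408 counts over all wells. edgeR called 4 of 10939 genes, Foxq1, F5, Clstn3 and Eva1b, all higher, which fall outside the rule for named genes and were chosen after their values were seen. In all 723 genes had an unadjusted p under 0.05. The older pipeline called 0 and DESeq2 1. For the lists, cameraPR and camera with an estimated correlation each called 0 of 24, with 4 and 2 at an unadjusted p under 0.05. The older pipeline called 5 lists, and hairpin wells of other targets as reference gave 4. The count was 2 without replicate 2, 1 without replicate 3, 9 without a filter on low counts and 28 with hairpin wells of other targets. Against mock wells, 3 of the 5 wells could be compared and gave 36 genes; against non-targeting wells the same 3 gave 1. Leaving out control wells 93 to 95 gave 41, the 4 genes included, with 2 lists called, trophoblast higher and ribosomal proteins lower (0 with an estimated correlation).

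Etv1, an ETS factor downstream of FGF signals, was the first of the 4 further targets taken for their high number of calls. Its own transcript did not pass, at 25.7 ± 25.4 in 5 wells against 35.2 ± 17.3 CPM in 25 control wells (-0.39 ± 0.39, adjusted p = 0.69), so these are the wells labelled Etv1. In them the cell adhesion protein Pcdh7 rose to 182 ± 34.2 against 42.2 ± 23.3 CPM (2.23 ± 0.26), the Notch coactivator Maml3 to 220.3 ± 69.6 against 72.1 ± 23.6 CPM (1.74 ± 0.19), and Irf2, Gab1, Zfp704 and Mid1 by log2 fold changes of 2.08 ± 0.33, 1.77 ± 0.31, 1.71 ± 0.24 and 1.59 ± 0.30. The surface protein Thy1 (-3.02 ± 0.62), Spon1 (-1.84 ± 0.34), Rangrf (-2.04 ± 0.40), which shares 90.7% of its exonic bases with another gene, and the DNA methyltransferase Dnmt3b (-0.89 ± 0.19) were lower.

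Of 20 Myc and nucleolar genes 4 fell in these wells (9 adjusted over the list alone; list adjusted p = 0.011 with an estimated correlation), the helicase Ddx21 (-0.62 ± 0.13) and Wdr43 (-0.63 ± 0.14) among them. Of 16 primed epiblast genes 3 fell (4, p = 0.049), and of 19 genes of the integrated stress response 1, Psat1 (-0.56 ± 0.15) (1, p = 0.049). Calls were lost with an estimated correlation for ribosomal proteins, with a fall of Rpl15 (-0.52 ± 0.12) among 24 (5, p = 0.15). The same held for heat shock, with falls of Hspe1 and Hspa8 among 13 (5, p = 0.48), DNA replication with a fall of Prim1 and a rise of Pola1, both of the primase complex, among 19 (1 higher and 3 lower, p = 0.077), and cholesterol synthesis with 0 of 19 called (1, p = 0.077). In all 178 genes rose and 79 fell of 11753. The older pipeline also called 110 of them. DESeq2 gave 300 calls, of which 173 were lower, and hairpin wells of other targets as reference gave 1 call, which was not among the 257. The median size of the 257 changes was 0.47 there (median SE 0.27) in place of 1.06 (0.25). Leaving out control wells 93 to 95 gave 612, and all 29 called named genes kept their call. The count fell to 46.3% without replicate 1, 60.3% without replicate 4 and 48.2% without replicate 5. It was 79 with named controls only. Against mock wells edgeR called 0 genes in the 2 of 5 wells that could be compared, with 905 at an unadjusted p under 0.05.

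Pa2g4 (Ebp1), a protein of ribosome assembly and growth, was clearly lowered, at 91.9 ± 104.7 in 8 wells against 580 ± 131.5 CPM in 36 control wells (-2.61 ± 0.26, adjusted p = 4.9e-10). The elongation factor Ell2 rose to 471 ± 585 against 113.9 ± 57.3 CPM (1.95 ± 0.25), the glucose transporter Slc2a3 to 5978 ± 1341 against 3033 ± 827 CPM (1.00 ± 0.13) and the syndecan Sdc2 to 297 ± 174 against 96.0 ± 41.5 CPM (1.53 ± 0.19). Lefty2, a Nodal inhibitor, fell to 27.7 ± 12.7 against 159 ± 118.8 CPM (-2.53 ± 0.51) and Cd3eap, a subunit of RNA polymerase I, to 12.3 ± 11.9 against 74.3 ± 59.2 CPM (-2.54 ± 0.55). Nucleolin, Ncl, fell to 597 ± 219 against 1105 ± 253 CPM (-0.86 ± 0.15) and Psat1, of serine synthesis, to 665 ± 81.3 against 1167 ± 267 CPM (-0.81 ± 0.14).

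All 13 list calls of the Pa2g4 knockdown were lost with an estimated correlation. The clearest counts were 4 falls among 20 Myc and nucleolar genes (8 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation) and 4 among 12 core pluripotency genes (5, p = 0.064), with Lin28a (-0.73 ± 0.17) as example. There were also 2 among 16 primed epiblast genes (6, p = 0.064), 2 among 13 heat shock genes (5, p = 0.24), and 2 rises among 21 glycolysis and hypoxia genes (2, p = 0.17). A fall of 1 gene was called in DNA replication, Rrm2 (4, p = 0.17), the integrated stress response, Psat1 (1, p = 0.16), Nodal and Activin targets, Lefty2 (2, p = 0.071), and FGF and ERK targets, Spry2 (2, p = 0.14). A rise of 1 was called in mitosis, Ccnb2 (5, p = 0.24), and actin and YAP targets, Tpm1 (7 and 1 lower, p = 0.096). The p53 response (0 of 18, 0 over the list alone, p = 0.40) and cholesterol synthesis (0 of 19, 0 over the list alone, p = 0.071) were called higher as lists only. In all 140 genes rose and 77 fell of 11166, and 62 were also called by the older pipeline. DESeq2 gave 242 calls, of which 100 were higher. Hairpin wells of other targets gave 9 calls, 7 shared, with Pa2g4 and Ell2 among them, the only 2 of 35 called named genes to keep their call. It was 230 without control wells 93 to 95, and 26 of the 35 kept their call. The main count fell to 56.7% without replicate 1 and 49.8% without replicate 3. It was 1282 with named controls only, 8 wells that all lie among wells 93 to 95.

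Psmc3ip (Hop2), a cofactor of meiotic recombination, was at 4.26 ± 6.63 CPM in 6 wells against 22.3 ± 15.6 CPM in 25 control wells (-2.16 ± 0.63, adjusted p = 0.0034 over targets and 0.070 over all genes). Pcdh7 rose to 202 ± 124.5 against 41.6 ± 23.4 CPM (2.32 ± 0.28), Acta2 to 256 ± 232 against 58.8 ± 45.3 CPM (1.95 ± 0.34) and Maml3 to 235 ± 94.1 against 88.5 ± 43.3 CPM (1.61 ± 0.23), while Spon1 (-1.79 ± 0.29), Psat1 (-0.72 ± 0.13) and Ddx21 (-0.76 ± 0.12) fell. Myc and nucleolar genes fell in 2 of 20 (6 adjusted over the list alone; adjusted p = 0.0025 with an estimated correlation), DNA replication genes in 2 of 19 (2, p = 0.013), Rrm2 and Pcna, and the integrated stress response in 1 of 18 (3, p = 0.011). Definitive endoderm genes rose in 2 of 9 (5, p = 0.011), Foxa1 (3.67 ± 0.74) and Gata6 (2.76 ± 0.68), neither called without replicate 5. Actin and YAP targets, with a rise of Tpm1 among 16 (2, p = 0.26), the primitive streak (0 of 9, 3 over the list alone, p = 0.12), heat shock (0 of 12, 4 over the list alone, p = 0.21) and ribosomal proteins (0 of 24, 4 over the list alone, p = 0.12) lost their call with an estimated correlation.

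Of 11415 genes 99 rose and 41 fell in the Psmc3ip wells, and 13 were also called by the older pipeline. RLE factors gave 100 higher and 25 lower, DESeq2 46 and 79, and hairpin wells of other targets gave 4 calls, 2 shared. None of the 24 called named genes kept its call there, with a median size of the 140 changes of 0.54 (median SE 0.25) in place of 1.16 (0.27). With control wells 93 to 95 left out the count was 275, and 22 of the 24 kept their call. The count was 46 without replicate 1, 92 without replicate 2, 93 without a plate term and 21 with named controls. Against mock wells, 3 of the 6 wells could be compared and gave 4 genes; against non-targeting wells the same 3 gave 5.

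Nfatc3, a calcineurin-dependent factor, did not pass for its own transcript, at 35.3 ± 26.2 in 6 wells against 52.8 ± 23.5 CPM in 18 control wells (-0.68 ± 0.38, adjusted p = 0.47). In the wells labelled Nfatc3, the protease Prss23 rose to 211 ± 77.4 against 52.7 ± 36.2 CPM (2.04 ± 0.28) and Acta2 to 290.1 ± 101.7 against 80.4 ± 37.1 CPM (1.89 ± 0.28), and Thy1 (-3.44 ± 0.63), the Ras family member Eras (-2.33 ± 0.56), the pluripotency gene Utf1 (297 ± 110.05 against 792 ± 266 CPM, -1.38 ± 0.21) and the chaperone Hsp90aa1 (-0.63 ± 0.12) were lower. Lists called lower were Myc and nucleolar genes with 1 of 19 called, Dkc1 (7 adjusted over the list alone; adjusted p = 0.26 with an estimated correlation) and primed epiblast with 2 of 16, Fgf5 and Dnmt3b (4, p = 0.12). So were core pluripotency with 1 of 12 (1 higher and 5 lower, p = 0.30), DNA replication with 1 of 20 (5, p = 0.26), the integrated stress response with 1 of 19 (2, p = 0.49), and heat shock with 1 of 13 (3, p = 0.61). Then came Nodal and Activin targets with 0 of 12 (5, p = 0.14) and FGF and ERK targets with 0 of 15 (0, p = 0.26). Actin and YAP targets rose in 2 of 16, Tpm1 (0.77 ± 0.15) and Ankrd1 (5, p = 0.26).

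Of 10896 genes 62 rose and 28 fell in the Nfatc3 wells, 28 of them also called by the older pipeline. DESeq2 gave 45 higher and 80 lower genes. Named controls, here 4 wells that all lie among wells 93 to 95, gave 414 in all. Hairpin wells of other targets gave 24 calls, 14 shared. None of the 25 called named genes kept its call there, and 22 did without control wells 93 to 95, where 83 genes rose and 40 fell. The count was 51 without replicate 3, 59 without replicate 4, 59 without replicate 5 and 55 without replicate 6.

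**Figure D4:**
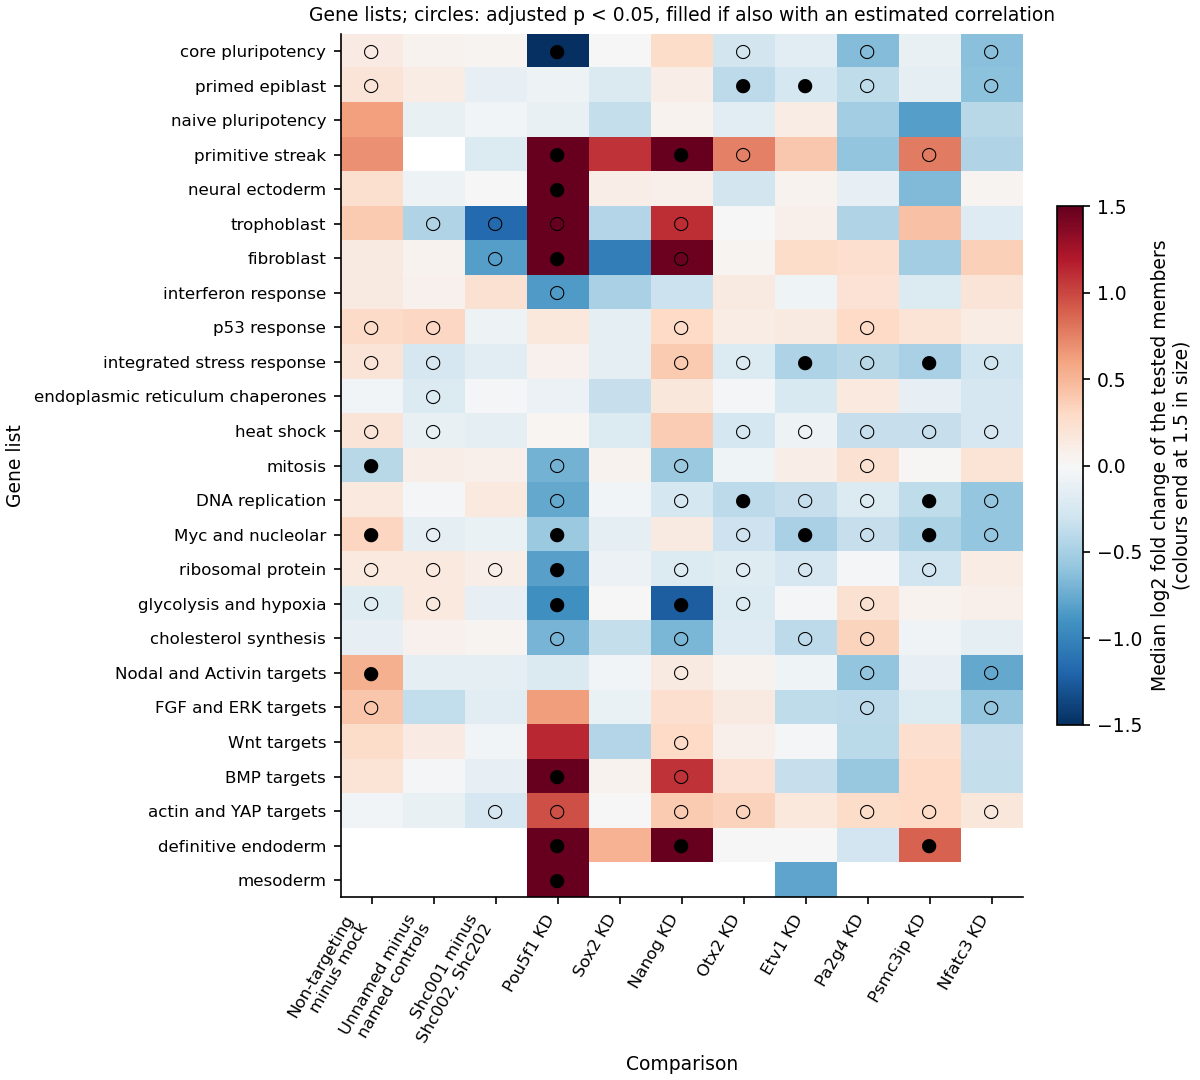
Median log2 fold change of the tested members of each gene list (rows) in the 3 control comparisons and the 8 knockdowns (columns), as a colour scale that ends at 1.5 in size. Open circles mark an adjusted p under 0.05 and filled circles those that also pass with an estimated correlation, 10 for Pou5f1 and 3 for Nanog.

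The last question was whether different hairpins against a gene gave similar profiles. Over 1077 pairs of wells with 1 target and different clones, the mean correlation of deviations from the control wells across 3934 genes was 0.157, against 0.142 ± 0.0026 (SD) in 1000 shuffles of the wells within plates (one-sided permutation test, p = 0.001, the smallest that the shuffles can give). Genes are not independent replicates in such a correlation. On different plates the mean was 0.0931 over 564 pairs against 0.0843 shuffled (p = 0.026), and on 1 plate 0.228 over 513 pairs against 0.206. Measured from the mean of the hairpin wells of the plate instead, the values were 0.00867 and -0.00918. The highest mean of a target was that of Pou5f1, 0.53 over 3 pairs.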

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

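The tests in this part of the control wells, among them wells 93 to 95, of feeder cells, of the depth of the Pou5f1 wells, the counts over other splits and the sham targets were chosen after the results were seen; so was the comparison of well positions on the same plates; those of well position over all plates, depth, hairpin activity and gene overlap were fixed earlier.

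In 6 named genes, 1 well stood apart from the rest of its group by more than the usual gap limit for its size. Of 90 groups of wells tested in this way, chance alone gives about 1 in 20. On the log2(CPM + 1) scale, Rab3b reached 7.83 in replicate 6 of the Otx2 knockdown, against 4.88 to 5.98 in the others. Among the wells labelled Etv1, Pcdh7 reached 7.93 in replicate 1 (7.34 to 7.46 in the others), Rangrf was at 0 in replicate 4 (3.05 to 3.84) and Tmem59l at 0.653 in replicate 2 (4.32 to 5.58). Gusb was at 0 in replicate 3 of the Pa2g4 knockdown (2.71 to 4.19), and Acta2 was at 6.75 in replicate 2 of the wells labelled Nfatc3 (8.08 to 8.60). Outside the fitted comparisons, 12 of 34 wells of 20 targets with too few wells to fit had less of the targeted transcript than every control well, and 0 had more.

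Some genes were called against the non-targeting wells in knockdowns of many targets. Acta2 was called higher in 34 and Utf1 lower in 29 of the knockdowns fitted, while the 100 sham targets drawn from control wells gave 0 with at least 10 calls. Unequal depth is argued against by a ratio of 1.03 between the median totals of hairpin and control wells. A score of this shared change was not higher in 55 targets with a lower transcript (0.638 ± 0.221, SD) than in 74 others (0.666 ± 0.244). The difference was -0.0283 (one-sided permutation test, p = 0.75). A transcript's call depends on its level and number of wells, and the score on the plate, so stronger action of hairpins stays undecided. A gradient along the plate stays open. Control wells numbered under 80 reached 0.173 of the mean of hairpin wells over all plates, but 27 of these 30 wells lie on the 4 plates with mock wells, where hairpin wells score lower. On those 4 plates the ratio was 0.287 (0.0835 ± 0.132, SD, n = 27, against 0.290 ± 0.332, n = 120), and control wells from well 80 on scored -0.0593 ± 0.148 (n = 38). A peculiarity of the control wells also stays open: on a score chosen on the 9 plates without mock wells, the mock wells of the other 4 plates scored 2.21 times as high as the hairpin wells there (0.643 ± 0.158, n = 36), so the control wells, rather than the knockdowns, may carry part of the change. Of the 36 mock wells 31 are numbered 1 to 8, so their score may reflect position too. A different state of control wells 93 to 95 stays open too: 63.8% of the 3870 genes called in all hairpin wells were called again without these wells, which may thus carry only part of the change. Of the control wells from 80 on, they scored -0.181 ± 0.101 (n = 12) and wells 80 to 92 -0.0031 ± 0.133 (n = 26). Acta2 was then called higher in 53 and Utf1 lower in 29.

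The Pou5f1 knockdown had higher levels of genes of the fibroblast list. Carried-over feeder cells are argued against, because Postn, Lum and Dcn together gave 9 counts against 4270 for Col1a1, a ratio of 0.00211. Low depth is argued against by the lowest total of the 3 wells, 1069520, which lies within the range of the control wells (414037 to 2222622). Loss of the epiblast state after loss of Pou5f1, the difference that the design names, remains as a hypothesis, and 466 of the 1276 genes were also called against hairpin wells of other targets.

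Sox2 had 0 counts in every well of its comparison, in cells that are grown as pluripotent. Reads shared with an exon of an overlapping gene are argued against, because 0% of its exonic bases lie in an exon of another gene. Loss of genes that lie wholly within another gene's span, as counting over whole gene bodies may produce, fits: 85.9% of 496 such genes had 0 counts, against 9.26% of 19916 others, so counts of nested genes cannot be read as expression. No biological explanation was tested.

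Chance was tested by drawing 100 splits of the wells of each comparison within plates, the real split included. It can be excluded for mock against non-targeting (1 split as large, 2229 genes, highest other 35), unnamed against named controls (1, 1444 and 9), Pou5f1 (1, 1276 and 259), Nanog (2, 161 and 198) and Otx2 (1, 140 and 12). For Sox2, 3 splits gave as many (4, highest other 8), so chance stays open. Sham targets gave at most 2 genes. With no change simulated in 5 other layouts the test made 0 to 18 calls, so 4 genes are a weak count. Etv1 (1, 257 and 254), Pa2g4 (1, 217 and 71), Psmc3ip (2, 140 and 233) and Nfatc3 (1, 90 and 15) were chosen for their high counts, so for them the splits do not exclude chance. For Shc001 the count was 0, which all 100 splits reach, so the splits say nothing. The splits with most genes held 2 of the 3 Pou5f1 wells (259), 2 of the 3 Nanog wells (198), 2 of the 6 Psmc3ip wells (233) and 0 of the 5 Etv1 wells (254) on the target side. Splits with 0 target wells on that side gave at most 48, 17, 1 and 254. Of wells 93 to 95 these top splits held 1, 1, 4 and 4 on that side. Wells 93 to 95 themselves, on the 11 plates without Pou5f1 or Nanog wells, gave 4573 genes, which 1 split reached (highest other 5). For the lists, 1 split gave as many calls over the 8 knockdowns, 4 of them chosen for their counts (78 real, highest other 37), and 1 over the 3 control comparisons (23 and 14). Of 40 splits of all hairpin and non-targeting wells, 1 gave as many genes as the real one (3870, highest other 17), and of 100 reassignments of targets 1 gave as many lower transcripts (55, highest other 7).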

How the results depend on the processing

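Tests chosen after the results were seen were the count of genes called by both edgeR pipelines, the count called by all 3 tests, the use of mock wells as reference, and leaving out control wells 93 to 95; the other alternatives were fixed before the data were examined. Without a depth minimum, or with at least 300000 counts per well, the comparisons described one by one kept the same wells and counts. With RLE size factors the total of genes called in a comparison moved by under 1.5 times in each. The lower genes of the Psmc3ip knockdown moved by more. The number of targets with a lower transcript lay between 44 and 65 under every alternative run, against 55. With RLE factors the calls shifted in direction. Unnamed against named controls gave 562 higher and 904 lower genes in place of 715 and 729, the Pou5f1 knockdown 1069 and 313 in place of 859 and 417, and the Psmc3ip knockdown 100 and 25 in place of 99 and 41. DESeq2, which uses similar factors, leaned the other way for these knockdowns, with 41.0% of the Pou5f1 calls and 36.8% of the Psmc3ip calls higher, so there the balance depends on the tool. For the unnamed controls it gave 46.2% higher, the same side as RLE.

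The older edgeR pipeline called fewer genes: 1244 for mock against non-targeting, 762 for unnamed against named controls, 569 for Pou5f1, 76 for Nanog, 37 for Otx2, 1.1e2 for Etv1 (62 higher and 50 lower), 62 for Pa2g4, 13 for Psmc3ip, 28 for Nfatc3 and 0 for Sox2, with 1 for Shc001 against the other named controls. It left 22 targets with at least 10 calls in place of 64, and 5 lists called for Sox2 in place of 0. Both pipelines called 1239, 760, 537, 68, 36, 110, 62, 13 and 28 genes in that order from mock to Nfatc3, and 0 for Sox2. All 3 tests called 1221, 718, 463, 59 and 36 from mock to Otx2, 62, 13 and 26 from Pa2g4 to Nfatc3, and 0 for Sox2. In simulation 18.0% to 33.3% of main calls and 1.61% to 4.95% of the older pipeline's were false. There main calls alone are less firm, but sham targets gave at most 2. DESeq2 called 712 genes for Pou5f1 (292 higher, 420 lower), 288 for Nanog (85 and 203), 1 for Sox2 and 38 for Shc001 (12 and 26). Its counts for the other comparisons stayed within 1.5 times, with 56 higher and 69 lower for Otx2, 300 in all with 173 lower for Etv1, 242 in all with 100 higher for Pa2g4, 46 and 79 for Psmc3ip, and 45 and 80 for Nfatc3.

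With no filter on low counts Shc001 gave 27 genes, Sox2 9, Nanog 251, and 1.1e2 targets had at least 10 calls (79.1%, against 47.8%). Without a plate term the unnamed controls gave 889 genes and Psmc3ip 93. With only named control hairpins as reference the counts were 456 for Otx2, 79 for Etv1, 1282 for Pa2g4, 21 for Psmc3ip and 414 for Nfatc3, and 100 targets had at least 10 calls. With only unnamed non-targeting wells, mock gave 1419 genes, Pou5f1 569, Sox2 0 and Nanog 24, and 42 targets had at least 10 calls. The cause was not tested. Both references hold fewer wells than the main one, and for Otx2, Pa2g4 and Nfatc3 all named wells are among those that stand apart.

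The reference made from hairpin wells of other targets moved most knockdowns: 536 genes for Pou5f1, 28 for Sox2, 0 for Nanog, 37 for Otx2, 1 for Etv1, 9 for Pa2g4, 4 for Psmc3ip, 24 for Nfatc3, and 24 targets with at least 10 calls. It called 4 lists for Sox2, 5 for Nanog, 2 for Etv1, 3 for Pa2g4, 2 for Psmc3ip and 1 for Nfatc3. Mock wells as reference gave 36 genes for 3 of 5 Sox2 wells, 800 for all 3 Nanog wells, 0 for 2 of 5 Etv1 wells and 4 for 3 of 6 Psmc3ip wells. The same wells gave 1, 161 and 5 against non-targeting wells for Sox2, Nanog and Psmc3ip. Etv1 had 905 genes at an unadjusted p under 0.05 in that edgeR test, and no other tool was run on it.

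Without control wells 93 to 95 the counts were 42 for the unnamed controls, 1 for Shc001, 2022 for Pou5f1, 41 for Sox2, 474 for Nanog, 355 for Otx2, 612 for Etv1 and 275 for Psmc3ip, and 93 targets had at least 10 calls. Mock and Pa2g4 stayed within 1.5 times. In the unnamed controls directions turned for endoplasmic reticulum chaperones (adjusted p = 0.922), heat shock (0.148), Myc and nucleolar genes (0.315), ribosomal proteins (0.814), and glycolysis and hypoxia, which was called lower (9.7e-05, 0.072 with an estimated correlation). Log2 fold changes there became 0.068 for Aars, 0.061 for Hsp90ab1, 0.094 for Hspd1, 0.042 for Hsph1, 0.0079 for Srm, 0.036 for Ddx21, -0.083 for Aldoa and -0.094 for Gapdh. With an estimated correlation 10 lists were called for Nanog, 9 for Pou5f1, 7 for Otx2, 7 for Etv1, 5 for Psmc3ip and 4 for mock.

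With an estimated correlation, camera called 3 lists for mock in place of 11, 0 in place of 8 for the unnamed controls, 0 in place of 4 for Shc001, 10 in place of 16 for Pou5f1, 3 in place of 15 for Nanog, 2 in place of 10 for Otx2, 3 in place of 7 for Etv1, 0 in place of 13 for Pa2g4, 4 in place of 8 for Psmc3ip, and 0 in place of 9 for Nfatc3. Of all list calls, 76 were lost with it. The older pipeline lost 2, core pluripotency in mock (adjusted p = 0.081) and Wnt targets in Nanog (0.073).

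Leaving out 1 well at a time gave 482 to 970 genes for Pou5f1, 1 to 6 for Sox2, 74 to 1.1e2 for Nanog (46.0% to 70.8% of the main count), 82 to 158 for Otx2, 1.2e2 to 248 for Etv1 (46.3% to 96.5%), 1.1e2 to 187 for Pa2g4 (49.8% to 86.2%), 46 to 1.4e2 for Psmc3ip (32.9% to 97.1%) and 51 to 89 for Nfatc3. All of these fits have fewer target wells, and some also lost the control wells of a plate: 15 in place of 31 for Pou5f1 without replicate 1, 24 in place of 33 for Sox2 without replicate 1 or 2, 36 in place of 45 for Otx2 without replicate 3, 4 or 8, and 27 in place of 36 for Pa2g4 without replicate 4 or 8.

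Directions turned mainly with other hairpin wells as reference, on the opposite side of 0. The lists were ribosomal proteins for Nanog (adjusted p = 0.469), the integrated stress response (0.434) and Myc and nucleolar genes (0.343) for Otx2, DNA replication for Etv1 (0.756), heat shock, DNA replication and Myc genes for Pa2g4 (each 0.729), and primitive streak and actin and YAP genes for Psmc3ip (each 0.743). Log2 fold changes became -0.18 for Utf1, 0.52 for Btg2, -0.031 for Hsp90aa1, -0.042 for Rpl11, -0.058 for Rpl7 and -0.0014 for Rpl19 in the comparison with mock, where the hairpin wells take the place of the non-targeting wells. They became 0.18 for Utf1 under Pa2g4 knockdown and -0.043 for Lhx1 under Pou5f1 knockdown. Without a plate term Rplp0 in the unnamed controls became -0.15. The cause was not tested.

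Among the called named genes, the older pipeline kept 231 of 345, DESeq2 314 of 345, other hairpin wells as reference 92 of 304, and the fits without wells 93 to 95 kept 291 of 345. Of 247 in knockdowns, 1.1e2 kept their call whichever well was left out. The mean correlation of same-target wells stayed above its shuffled value in every alternative run, at p = 0.001 except for wells on different plates (p = 0.026). No paired analysis was possible because replicate numbers were given in accession order and the labels carry none; plate entered each fit as a covariate. With 3 wells against 31, simulated 2-fold changes were recovered for 16 of 100 genes and 4-fold changes for 50 of 100; with 3 against 16, for 24 and 58.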

Other observations

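All of the pooled comparisons in this part were chosen after the results of the single knockdowns were seen, as were the list of transcripts that recurred and the fits without control wells 93 to 95; the relations of the score with well number and depth were fixed earlier.

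When all 610 hairpin wells were set together against the non-targeting wells of the 13 plates, the primitive streak and definitive endoderm lists were higher, and the Myc and nucleolar, ribosomal protein and DNA replication lists lower. edgeR called 2032 higher and 1838 lower genes of 11741, most by little: the median size of a called log2 fold change was 0.30, and 74 genes exceeded 1. Foxq1 was 2.36 higher on the log2 scale, Acta2 1.64, Meis2, a homeobox factor, 1.48, Chrd 1.37 and Nr2f2 1.33. Thy1 (log2 fold change -1.27), Sfpq, a splicing factor (-0.93), and Fgf15 (-0.83) were lower. Of the primitive streak list 9 of 11 members rose and 1 fell (9 and 1 adjusted over the list alone), and of the definitive endoderm list 9 of 11 (9). Of the Myc and nucleolar list 19 of 20 fell (19), of the ribosomal proteins 19 of 24 (19), and of the DNA replication genes 12 of 19 fell and 1 rose (12 and 1). Of the actin and YAP targets 12 of 16 rose (12 higher and 1 lower over the list alone). No estimated correlation was run for these pooled lists. Control wells 93 to 95 of each plate stand apart from the others. Without them 2379 genes were higher and 1758 lower, with 63.8% of the 3870 among them. Of the genes named above, only Sfpq lost its call (-0.093). The primitive streak list then had 8 of 11 members higher and 1 lower (8 and 1 adjusted over the list alone), definitive endoderm 6 and 1 of 11 (6 and 1), and Myc and nucleolar genes 12 of 20 lower (13). Fibroblast genes had 6 of 8 higher and 1 lower (6 and 2), and trophoblast genes 9 of 11 higher (10), and neither of these lists was called with all control wells.

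The 4 plates with mock wells allow the hairpin wells to be set against both kinds of control. There, hairpin wells differed from non-targeting wells in 1929 genes and from mock wells in 3031, and non-targeting from mock wells in 2229. The primitive streak list was higher in hairpin wells against both references, with 9 of 11 members called each time (9 higher and 1 lower adjusted over the list alone in each). The cameraPR adjusted p was 1.6e-16 and 7.4e-10, with the preset correlation. Foxq1 was 3.89 higher against non-targeting and 3.46 higher against mock wells, and Acta2 2.56 and 1.89. Other genes took opposite sides: Camk1d, a calcium-dependent kinase, was 1.05 higher than in non-targeting wells but 1.40 lower than in mock wells (log2 fold change -1.40), and Fgf15 was 0.83 lower than in non-targeting wells (-0.83) and 0.57 higher than in mock wells. Myc and nucleolar genes likewise had 5 of 20 members lower against non-targeting wells (5 adjusted over the list alone) and 9 of 20 higher against mock wells (9).

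Across the knockdowns fitted one by one, BC064078 was called higher in 44, Acta2 in 34, Ly6e, Pcdh7 and Tpm1 in 28 each, Foxq1 in 23 and Camk1d in 15. Utf1 was called lower in 29, Psat1 in 18, Pim2, a kinase, in 17 and Dnmt3b in 16. Without control wells 93 to 95 Tpm1 was called higher in 58, Acta2 in 53, BC064078 in 52 and Foxq1 in 22, and Dnmt3b lower in 37, Utf1 in 29 and Psat1 in 24. With hairpin wells of other targets as reference, Camk1d was called in 10, 9 of them among the 15, and each of the others in at most 2. These knockdowns share the control wells of their plates. Among the hairpin wells, the score of the shared change had a Spearman's rho of -0.110 with well number (r = -0.10, permutation p = 0.0083, -0.106 without the 2 wells farthest from the median, rho between -0.49 and 0.14 within single plates). With the logarithm of the total count it had a rho of 0.240 (r = 0.311, permutation p = 0.0001, the smallest that the permutations can give, 0.288 without the 2 farthest wells, rho between -0.31 and 0.59 within plates). Neither relation kept its sign in all 13 plates.

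Total counts varied by target: relative to the control wells of its plate, the 1 Tfam well had a log2 ratio of -2.13, and the medians over 3 wells were -0.67 for Zc3hc1 and -0.59 for Trim28. In gene structure, 12 of 19 protein-coding genes whose exonic bases are all shared with another gene had 0 counts (63.2%), against 11.0% of the rest.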
